A study of Mus musculus with 2 samples.

How the data were processed

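Livers of C57BL/6 mice were perfused with collagenase, hepatocytes were collected by centrifugation at low speed, and nuclei were released with the detergent CHAPS. Per the labels, 1 library came from animals fasted for 24 h and 1 from animals fed ad libitum, each from 2 mice, made with the 10x 3' v3.1 chemistry. The deposited files hold raw UMI counts per gene and barcode; per the submitters' processing notes, the authors made them with Cell Ranger 5.0.0 on GRCm38. The annotation used, whether intronic reads were counted, and how barcodes were called are not given in the sources used here, nor is the handling of strand and of reads shared between copies. Values were checked to be whole and at least 1. The files list 32285 genes, of which 40 share a symbol with another.

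Nuclei with at least 300 genes and at most 5% mitochondrial counts were kept. Scrublet called 2 of 5616 and 0 of 3665 nuclei as doublets (0.0356% and 0%). Whether it worked here was not tested. With calls this few, doublets may remain, so an alternative left out the 5% with the highest scores. Counts were scaled to 10000 per nucleus, and 2000 variable genes, 30 components, 15 neighbours and Leiden clustering at resolution 1.0 gave 14 clusters over both libraries. A cluster was named for a class other than hepatocytes if at least 3 of its markers stood at 10 CPM or more and at 4 times their level in all other nuclei. Clusters with no such class and at least 3 hepatocyte markers at 10 CPM or more were called hepatocyte-like, so that name rests partly on the lack of another; 2 of them had Onecut1, also in the cholangiocyte list, and 1 had Rgs5, also in the stellate list, among their leading genes, and an alternative left these clusters out (2678 nuclei of the library labelled fasted left). The sums over hepatocyte-like nuclei held 5105 and 3421 nuclei and 22597954 and 19029222 UMIs.

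Raw counts were summed per gene over the nuclei of each class and library and scaled to CPM of nuclear-encoded counts (totals 22257707 and 18661676). Each log2 ratio is labelled fasted over labelled fed, with an exact conditional binomial interval; a library at 0 was set to a floor of 3 counts. CPM intervals are exact Poisson, shares have exact Clopper-Pearson intervals, and list medians have order-statistic intervals. Lists used members with at least 50 UMIs over both libraries. With 1 library per group, no test, p-value or standard error was computed from nuclei. Each list median was set beside 10000 random lists of the same size matched on expression within 100 ranks.

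The gene lists, the markers, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were 24 fixed genes, the 12 highest and 12 lowest by ratio among genes with at least 200 UMIs and 10 CPM in a library (without mitochondrial, ribosomal, listed sex chromosome and unnamed genes), and up to 2 highest and 2 lowest per list. Some genes that this rule names are not reported here, which left 120; they stay in their lists. The 25 lists covered fatty acid oxidation, other PPARA targets, gluconeogenesis, fasting hormones, fatty acid synthesis, cholesterol, bile acids, urea cycle, pericentral and periportal landmarks, growth hormone, the clock, autophagy, unfolded protein response, acute phase, plasma proteins, lipid droplets, glycogen, xenobiotics, oxidative phosphorylation, immediate early genes, cell cycle, male-biased and female-biased genes and sex chromosome genes.

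The zonal score was the mean of 10 periportal minus 12 pericentral genes, scaled within each library; score genes are not reported as zonal results. Nuclei were split into 3 equal bins, and genes needed 20 UMIs per bin and library. Endothelial-like and stellate-like nuclei were compared in the same way, and as an alternative genes were left out unless they stood at 5 times the level that hepatocyte RNA would bring in at least 1 library; since a gene can pass in 1 library while free RNA carries much of it in the other, an alternative that needs both libraries was added after seeing the data. Shares of nuclei with a UMI were taken after thinning to 1732 UMIs, the 10th percentile of the shallower library, which left out 509 and 502 hepatocyte-like nuclei.

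The calculation was tested on simulated data of 12702 genes. The interval held the true value for 95.1% of unchanged genes and for 96% to 100% of genes set to differ, and in the zonal step for 95.0%. Of 100 unchanged lists, 95% lay inside the central range. The simulated counts were Poisson draws around summed counts, with no variation between nuclei and no error in placing them in bins. They check the code and not how well the intervals hold for real nuclei. Alternatives were TMM (edgeR 4.0.16) and DESeq2 1.42.0 scaling, a total with mitochondrial genes, equal weight per nucleus, all nuclei, a stricter filter (1000 genes, 1% mitochondrial) and none, doublets kept, thinning, other count minimums, other clustering resolutions (0.4 and 2.0), 5 zonal bins, a score without genes of fasting lists, and thinning to 2544 UMIs. Added after seeing the data were the alternatives without the highest doublet scores, without low-depth clusters, without the clusters with Onecut1 or Rgs5, and with nuclei of 3000 to 8000 UMIs and at most 2% mitochondrial counts. Python 3.11.15, scanpy 1.11.5, scipy 1.17.1 and R 4.3.3 were used. Coordinates are from the GENCODE annotation of GRCm38.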

Results

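Nuclei from mouse liver were counted in 2 droplet libraries, 1 labelled as coming from animals fasted for 24 h and 1 labelled as fed ad libitum. Each library pooled material from 2 mice aged 8 weeks, so there was 1 library per group and no replicate. The library labelled fasted held 5668 barcodes and 25622043 UMIs, with a median of 3552.5 UMIs and 1734 genes per barcode. The library labelled fed held 5627 barcodes and 23139148 UMIs, with a median of 2502 UMIs and 1300 genes. Mitochondrial transcripts took a median of 1.71% of a barcode's UMIs in the library labelled fasted and 3.73% in the library labelled fed, and 52 (0.917%) against 1962 (34.9%) barcodes lay over the limit of 5%. After filtering, 5614 and 3665 nuclei were kept, at median depths of 3559.5 and 3742 UMIs. All intervals are 95% intervals. Those of single genes and of shares cover counting error only, and those of list medians reflect the spread between the members of a list. None of them says anything about differences between animals, and no test was made.

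Hepatocyte-like nuclei, which carried Alb, Apob and other hepatocyte genes and no set of markers of another class, made up 90.9% (exact binomial interval 90.2 to 91.7) of kept nuclei in the library labelled fasted and 93.3% (92.5 to 94.1) in the library labelled fed. Endothelial-like nuclei made up 5.52% (4.94 to 6.15) and 3.03% (2.498 to 3.64), and stellate or fibroblast-like nuclei, the mesenchymal cells of the liver, made up 2.99% (2.56 to 3.47) and 3.38% (2.82 to 4.02). A small unnamed cluster held 31 and 9 nuclei. Without the filter on mitochondrial share, which removed many more barcodes from the library labelled fed, the endothelial-like shares were 5.38% and 4.30%. Apart from 5 and 4 nuclei of the library labelled fasted, the hepatocyte-like nuclei of the 2 libraries fell into separate clusters, while endothelial-like and stellate-like nuclei of both libraries shared theirs.

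The main question of the design is what a 24 h fast does to gene expression in liver cells. In hepatocyte-like nuclei the genes of fatty acid synthesis and of cholesterol synthesis were higher in the library labelled fasted, and the target genes of PPARA, the nuclear receptor that turns on fat oxidation in fasting, were lower. The list of fatty acid synthesis and glucose use genes driven by SREBP1 and ChREBP had a median log2 ratio (labelled fasted over labelled fed) of 1.76 (1.26 to 3.07), with 27 of 29 measured members higher. The list of PPARA targets other than the oxidation enzymes had a median of -2.76 (-4.23 to -1.18), with 0 of 21 higher, or 4 of 21 under TMM scaling. These directions run against the labels as textbook physiology would have them, so each library is named by its label throughout and was not reassigned.

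Scaling mattered for small differences. Over 12082 genes with enough counts, the median log2 ratio was -0.45 when libraries were scaled to their nuclear-encoded total and -0.01 with TMM factors. A ratio near -0.45 is therefore the middle of all genes, but that middle depended on expression. Random lists matched on expression had medians of -0.02 for fatty acid oxidation, 0.04 for gluconeogenesis and -0.79 for the cell cycle. Directions of lists and genes that turn under TMM or DESeq2 scaling are named where they are given.

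Genes that convert glucose to fat were among the most different. Fasn, fatty acid synthase, stood at 394 CPM (385.7 to 402.2) in the library labelled fasted and 14.2 CPM (12.5 to 16.0) in the library labelled fed, a log2 ratio of 4.80 (4.62 to 4.98). Fasn, ENSMUSG00000025153, lies on chromosome 11 from 120805846 to 120824547, minus strand, in GRCm38. Srebf1, which encodes SREBP1, was at 166 and 12.3 CPM (3.76). Acly, which makes cytosolic acetyl-CoA, was at 688 and 39.8 CPM. The desaturase gene Scd1 was at 3118 and 453 CPM (2.78), and Pklr, the liver pyruvate kinase and a ChREBP target, at 220 and 16.6 CPM (3.73). The Pklr ratio was smaller without the clusters with Onecut1 or Rgs5 among their leading genes, as given with the alternatives. Thrsp, a lipogenic regulator, was at 1274 and 22.8 CPM (5.81). Pnpla3, a lipid droplet protein induced by SREBP1, had 1559 against 4 UMIs (8.35, 6.99 to 10.23). The members with the lowest ratios were G6pdx (-1.15, on 22 and 41 UMIs) and Agpat2 (-0.26), whose direction turned to 0.18 under TMM scaling.

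The SREBP2 list of cholesterol synthesis and uptake had a median log2 ratio of 1.86 (0.87 to 2.73), with 24 of 25 members higher in the library labelled fasted. Of these, 18 were at least 1.5 times higher and 0 were as much lower. Ebp, a late sterol isomerase, had the lowest ratio, -0.16, and turned to 0.28 under TMM scaling.

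PPARA target genes lay on the other side. Cyp4a14, a fatty acid omega-hydroxylase, stood at 7.10 CPM (6.04 to 8.30) in the library labelled fasted and 1884 CPM (1864 to 1903) in the library labelled fed, a log2 ratio of -8.05 (-8.29 to -7.83) and 265-fold higher in the latter. Cyp4a14, ENSMUSG00000028715, lies on chromosome 4 from 115486200 to 115496142, minus strand. Its neighbour Cyp4a10, from 115518264 to 115533649, was at 14.1 and 990 CPM (-6.13). Pdk4, which blocks pyruvate oxidation, was at 1.71 and 13.5 CPM (-2.98), the hormone gene Fgf21 at 1.57 and 12.7 CPM (-3.01) and Angptl4, an inhibitor of lipoprotein lipase, at 41.5 and 91.5 CPM (-1.14). The acyl-CoA thioesterase genes Acot1 and Acot3 had log2 ratios of -5.05 and -5.91, the latter on 4 and 202 UMIs. Cyp4a and Acot genes are families of close copies, and how reads shared between copies were counted is not given in the sources used here.

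The list of fatty acid oxidation and ketogenesis had a median of -1.20 (-1.40 to -0.78), with 0 of 22 members higher, or 3 of 22 under TMM scaling, where the median was -0.76. Ehhadh, a peroxisomal oxidation enzyme, was at 31.5 and 198 CPM (-2.65), and the isomerase gene Eci1 at 25.3 and 135 CPM (-2.41). Cpt1a, for fatty acid entry into mitochondria, lay near the middle of all genes, at 575 and 749 CPM (-0.38). It was below the median of random lists matched on expression to its list (-0.02), and turned to 0.057 under TMM scaling.

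Genes of glucose output and of the response to fasting hormones went both ways. The gluconeogenesis list had a median of -0.40 (-0.59 to 0.04), which turned to 0.03 under TMM scaling, and 4 of 16 members were higher in the library labelled fasted. Pck1, the rate-limiting enzyme of the pathway, on chromosome 2 from 173153048 to 173159273, plus strand, stood at 2086 and 2121 CPM (-0.02, -0.04 to -0.00), and turned to 0.41 under TMM scaling. G6pc, which releases free glucose and is also induced by ChREBP, was at 2231 and 478 CPM (2.22). Gpt, an alanine aminotransferase, was at 61.2 and 126 CPM (-1.04). The list of genes induced by glucagon, FOXO and glucocorticoids had a median of 0.23 (-0.18 to 0.89), with 15 of 25 members higher; under TMM scaling the median was 0.66 and 22 members were higher. In it, Nr4a1, an immediate early nuclear receptor, had a log2 ratio of 2.87, Lpin1, a phosphatidate phosphatase, 2.77, and Cebpd, a transcription factor, -3.45. The coactivator gene Ppargc1a was at 310 and 395 CPM (-0.35), turning to 0.086 under TMM scaling, and Igfbp1, a FOXO1 target, was at 281 and 196 CPM (0.52).

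**Figure D1:**
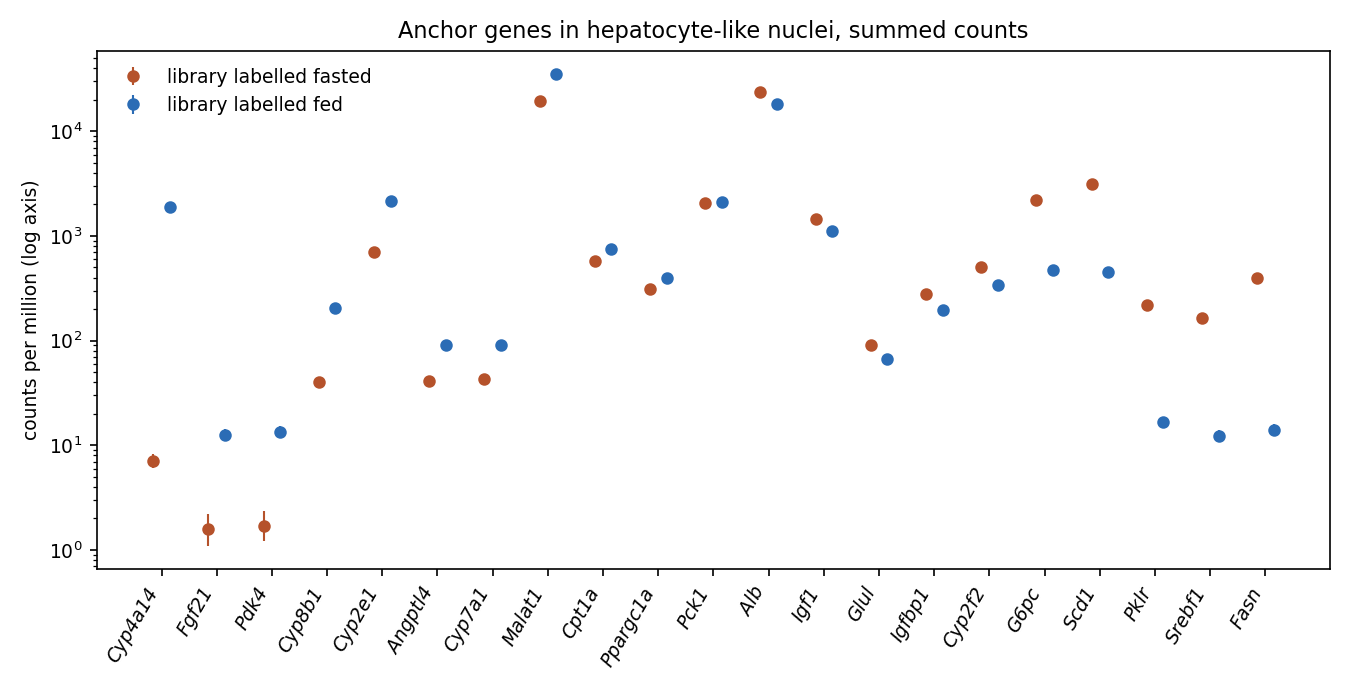
CPM, scaled to nuclear-encoded UMIs, in hepatocyte-like nuclei for genes fixed in advance, on a log axis, for the libraries labelled fasted and fed; points are 1 library each and bars are exact Poisson 95% intervals. Fasn stood at 394 and 14.2 CPM and Cyp4a14 at 7.10 and 1884 CPM, while Pck1 lay at 2086 and 2121 CPM and changed direction with the scaling.

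Nuclear genes of oxidative phosphorylation were lower in the library labelled fasted, with a median of -1.08 (-1.22 to -0.86) and 0 of 30 members higher, or 1 of 30 under TMM scaling. Cycs, cytochrome c, had a log2 ratio of -1.64 and Ndufa5, a subunit of complex I, -1.50. The median was -0.46 among nuclei with at least 1000 genes and at most 1% mitochondrial counts, and the share of mitochondrial counts differed between the libraries, at medians of 1.68% and 2.56% of UMIs over all hepatocyte-like nuclei. Lipid droplet, lipolysis and fat uptake genes had a median of -1.09 (-1.53 to -0.40), with 5 of 23 members higher, or 7 under TMM scaling. G0s2, an inhibitor of lipolysis, was at 22.0 and 454 CPM (-4.37), and Fabp4, a fatty acid carrier of fat and endothelial cells, had 9 and 104 UMIs. Acsl4, an acyl-CoA synthetase, was higher in the library labelled fasted (0.80), as was the monoglyceride lipase gene Mgll (0.52).

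Genes for secreted plasma proteins and lipoproteins had a median of -0.32 (-0.90 to -0.12), with 6 of 25 members higher; the direction turned to 0.12 under TMM scaling. Apoa4, an apolipoprotein, was at 43.7 and 1173 CPM (-4.75), and Rbp4, the retinol carrier, at 1793 and 6550 CPM (-1.87). Alb, albumin, had a log2 ratio of 0.37. The acute phase list had a median of -0.07 (-0.55 to 0.43), turning to 0.37 under TMM scaling, with Hamp, which encodes hepcidin, at -2.18 and Steap4, a metalloreductase, at 2.11. The urea cycle and amino acid breakdown list had a median of -0.12 (-0.41 to 0.19), which turned to 0.32 under TMM scaling. In it, Tat, tyrosine aminotransferase, had a log2 ratio of 1.51, Glud1, glutamate dehydrogenase, 1.58, and Oat, ornithine aminotransferase, -2.85.

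Bile acid genes went both ways, with a median of -0.18 (-0.79 to 0.48) that turned to 0.26 under TMM scaling. Cyp8b1, the 12-alpha-hydroxylase, was at 40.7 and 206 CPM (-2.34), and Cyp7a1, the rate-limiting enzyme of the classic pathway, at 42.8 and 91.6 CPM (-1.10). Cyp7b1, of the alternative pathway, was at 1795 and 552 CPM (1.70, but 0.28 without the clusters with Onecut1 or Rgs5 among their leading genes), and Abcb11, the canalicular bile salt export pump, at 797 and 194 CPM (2.04). Xenobiotic metabolism genes had a median of -0.24 (-0.96 to 0.40), turning to 0.19 under TMM scaling. Cyp2c70, which makes muricholic acids in mice, was at 886 and 12.8 CPM (6.12), and Nr1i3, the nuclear receptor CAR, at 95.1 and 522 CPM (-2.46). The Cyp2c70 ratio was also smaller without the clusters with Onecut1 or Rgs5 among their leading genes, as given with the alternatives.

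Landmark genes of the liver lobule differed within each list. The pericentral list, genes expressed near the central vein, had a median of -0.82 (-1.61 to 0.45). Cyp2e1 was at 707 and 2156 CPM (-1.61), Tbx3 had 51 and 600 UMIs (-3.81) and Axin2 22 and 179 UMIs (-3.28), the latter a direct target of Wnt signalling. Glul, glutamine synthetase, was at 90.5 and 66.2 CPM (0.45), and Cyp2c29 at 569 and 83.5 CPM (2.77). The periportal list had a median of 0.21 (-0.28 to 0.58), with Sds, serine dehydratase, at 1.01, Cyp2f2 at 0.58 and Hal, histidine ammonia-lyase, at -1.63.

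The growth hormone and IGF list had a median of 0.25 (-0.11 to 1.47). Egfr, the EGF receptor gene, was at 12310 and 3583 CPM (1.78), and Lifr, the LIF receptor gene, at 600 and 121 CPM (2.31). The Lifr ratio was smaller without the clusters with Onecut1 or Rgs5 among their leading genes, as given with the alternatives. Igf1 was at 1452 and 1110 CPM (0.39) and Igfbp2 at 411 and 974 CPM (-1.24). The list of unfolded protein and amino acid stress genes had a median of 0.19 (-0.20 to 0.86), with Ern1, the stress sensor IRE1, at 2.24 and Asns, asparagine synthetase, at -3.18 on 8 and 61 UMIs. The circadian list had a median of -0.09 (-0.84 to 0.31), turning to 0.35 under TMM scaling, with Bhlhe40 at 2.70 and Per3 at -1.42. The autophagy and lysosome list had a median of -0.02 (-0.52 to 0.14), turning to 0.42, with Ulk1, an autophagy kinase, at 1.47 and Ctsl, a lysosomal protease, at -1.73. The glycogen list had a median of 0.04 (-0.76 to 0.64), with Gbe1, the branching enzyme, at 2.42 and Ppp1r3b, which targets a phosphatase to glycogen, at 2.48. Immediate early and dissociation stress genes had a median of 1.13 (-0.40 to 1.95), with Atf3 at 3.86, Fos at 2.98, and Hspa8, a heat shock protein gene, at -0.96, which turned to 0.35 among nuclei with at least 1000 genes and at most 1% mitochondrial counts. The cell cycle list, with 9 measured members, had a median of -0.41 (-0.75 to 1.40) that turned to 0.03 under TMM scaling.

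Male-biased liver genes had a median of 0.74 (-0.38 to 1.76), with Hsd3b5, a steroid dehydrogenase of male liver, at 97.3 and 1.98 CPM (5.62); without the clusters with Onecut1 or Rgs5 among their leading genes these were 0.46 and 4.70. Female-biased genes, with 6 measured members, had a median of -1.14 (-5.91 to 1.65), which ranged from -2.50 to -0.70 over 15 alternatives. The sex chromosome list had a median of 0.33 (-0.04 to 0.48). The Y-linked gene Eif2s3y was at 87.3 and 89.2 CPM (-0.03), and Kdm5d at 44.8 and 46.1 CPM (-0.04); both turned positive under TMM scaling, to 0.41 and 0.40. Malat1, a nuclear noncoding RNA, was at -0.85.

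Among the 12 genes with the highest ratios were also Chrna4, an acetylcholine receptor subunit (332 and 1 UMIs, 8.12, 5.63 to 13.43), Slc10a2, a bile acid transporter (4.31), Slc22a28 (4.41), Aqp8, a water channel (4.09), and Pdgfrl (4.04). Among the 12 with the lowest were Ntf3, a neurotrophin (2 and 494 UMIs, -8.20, -11.25 to -6.34), Fut2, a fucosyltransferase (-5.77), Ribc1 (-5.67), Wdfy4 (-5.36), Zbed5 (-5.02), Cyp4a31 (-4.83) and Nhs (-4.79).

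Against 10000 random lists matched for size and expression, the medians of the SREBP1 and ChREBP, SREBP2, and immediate early lists lay at the highest percentile, 100, and that of the male-biased list at 99.99. Those of the fatty acid oxidation, other PPARA target, lipid droplet and oxidative phosphorylation lists lay at percentile 0. Toward the ends also lay the pericentral list at 1.19, the gluconeogenesis list at 2.82 and the unfolded protein list at 98.58. These percentiles describe the 2 libraries; genes are not replicates, and the libraries differ in animals as well as in label.

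**Figure D2:**
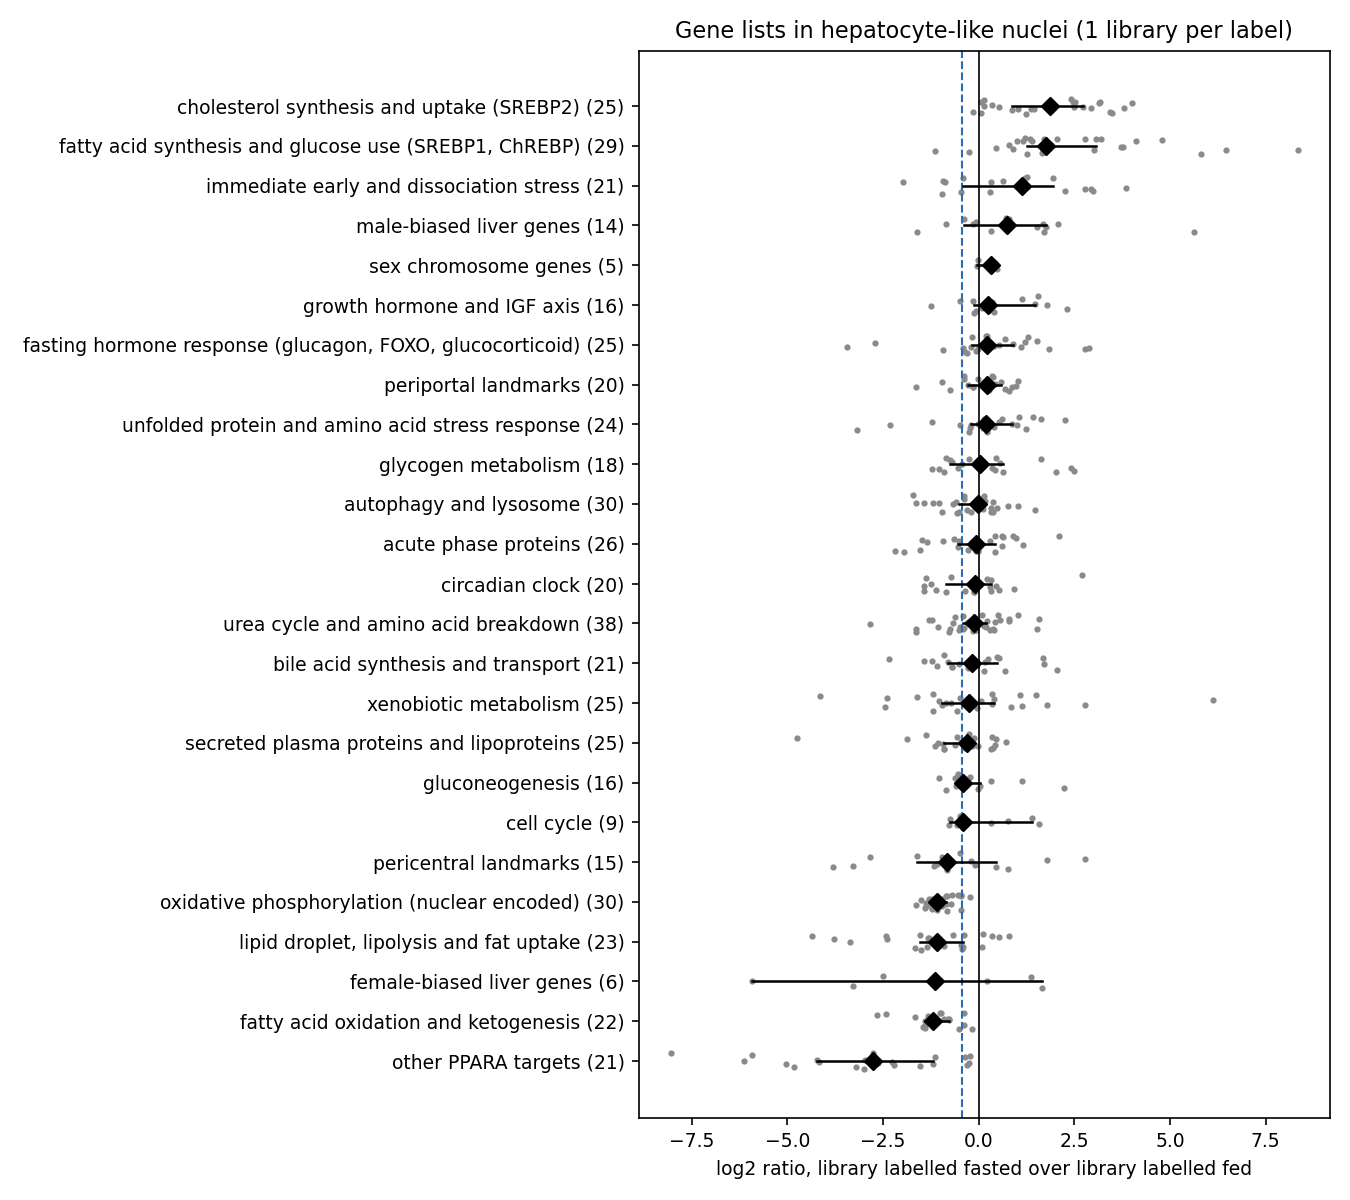
Log2 ratio of CPM, library labelled fasted over library labelled fed, for each gene list in hepatocyte-like nuclei; grey dots are members, diamonds are medians with 95% order-statistic intervals, and the dashed line is the median of all genes at -0.45. The SREBP2 list had the highest median at 1.86 and the list of other PPARA targets the lowest at -2.76, and the plasma protein list at -0.32 turns direction under TMM scaling.

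The share of nuclei with a UMI asked whether a difference in level lay in many nuclei or few. With each nucleus thinned to 1732 UMIs, 95.4% of hepatocyte-like nuclei in the library labelled fed had a UMI of Cyp4a14, against 1.15% in the library labelled fasted. In endothelial-like and stellate-like nuclei, which should lack the gene, the shares were 95.9% and 1.47%, so neither hepatocyte share exceeded the share in the other classes; free RNA, doublets and misplaced nuclei were not told apart as its source. Fasn was seen in 46.8% of hepatocyte-like nuclei in the library labelled fasted and 2.91% in the library labelled fed, with 38.8% and 2.92% in the other classes, and G6pc in 95.3% and 48.8%, with 86.2% and 28.7%. Median depths before thinning were 3610 and 3846 UMIs in hepatocyte-like nuclei and 2836 and 2383 in the other classes. Fasn in the library labelled fasted, and G6pc in both, were above the share in the other classes, and Fasn in the library labelled fed was not.

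The zonal comparison asked where along the lobule the libraries differ. Hepatocyte-like nuclei were ranked from central to portal by landmark genes and divided into 3 equal bins per library. Some of these landmark genes, such as Cyp2e1, Tbx3 and Axin2, themselves differed between the libraries. Equal bins therefore need not cover the same positions in both libraries, and whether they did was not tested. The SREBP2 list differed most, with log2 ratios larger in the central bin. Its members' ratios were lower in the portal than in the central bin by a median difference of -0.71 (-1.01 to -0.47), and 1 of 25 members had the larger ratio in the portal bin. Cyp2c29 had a log2 ratio of 3.25 in the central bin and 1.87 in the portal bin, a difference of -1.38 (-1.59 to -1.17). Thrsp (-0.98) likewise had its larger ratio in the central bin. Nr1i3, lower in the library labelled fasted in all 3 bins, had a log2 ratio of -2.05 in the central and -2.94 in the portal bin (difference -0.89), so the libraries differed more in the portal bin.

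The immediate early list had a median difference of 0.24 (-0.09 to 0.75), an interval that spans 0, but Atf3 and Fos in it had larger ratios in the portal bin. The log2 ratio of Atf3 was 3.33 in the central and 5.06 in the portal bin, a difference of 1.73 (1.24 to 2.23), and that of Fos was 2.36 and 4.08. Neither gene rose toward the portal bin in the library labelled fasted (Atf3 368 and 246 CPM, Fos 94.9 and 80.9 CPM). The larger portal ratios came with lower portal levels in the library labelled fed (Atf3 36.7 and 7.37 CPM, Fos 18.5 and 4.79 CPM). Ppargc1a had a ratio of -0.72 in the central and -0.01 in the portal bin, a difference of 0.71 (0.59 to 0.83). The SREBP1 and ChREBP list had a median difference of -0.04 (-0.32 to 0.03), and 9 of 28 members had the larger ratio in the portal bin. Of its members, Acly (-0.79, -1.08 to -0.51), Pklr (-0.75, -1.17 to -0.33), Fasn (-0.53, -0.98 to -0.08) and Scd1 (-0.35, -0.43 to -0.27) had smaller ratios there, as Thrsp did. The list of other PPARA targets had a median difference of -0.19 (-0.44 to -0.15), and Cyp4a14 alone -0.32 (-0.85 to 0.22). Over 9553 genes the median difference was 0.07, with 5th and 95th percentiles of -0.53 and 0.59. Fasn, at the edge, Scd1 and Cyp4a14 lay within that ordinary spread. Bins are ranges of a score and not cell types: 844 nuclei (16.5%) in the library labelled fasted and 542 (15.8%) in the library labelled fed lay within 0.1 SD of a boundary.

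**Figure D3:**
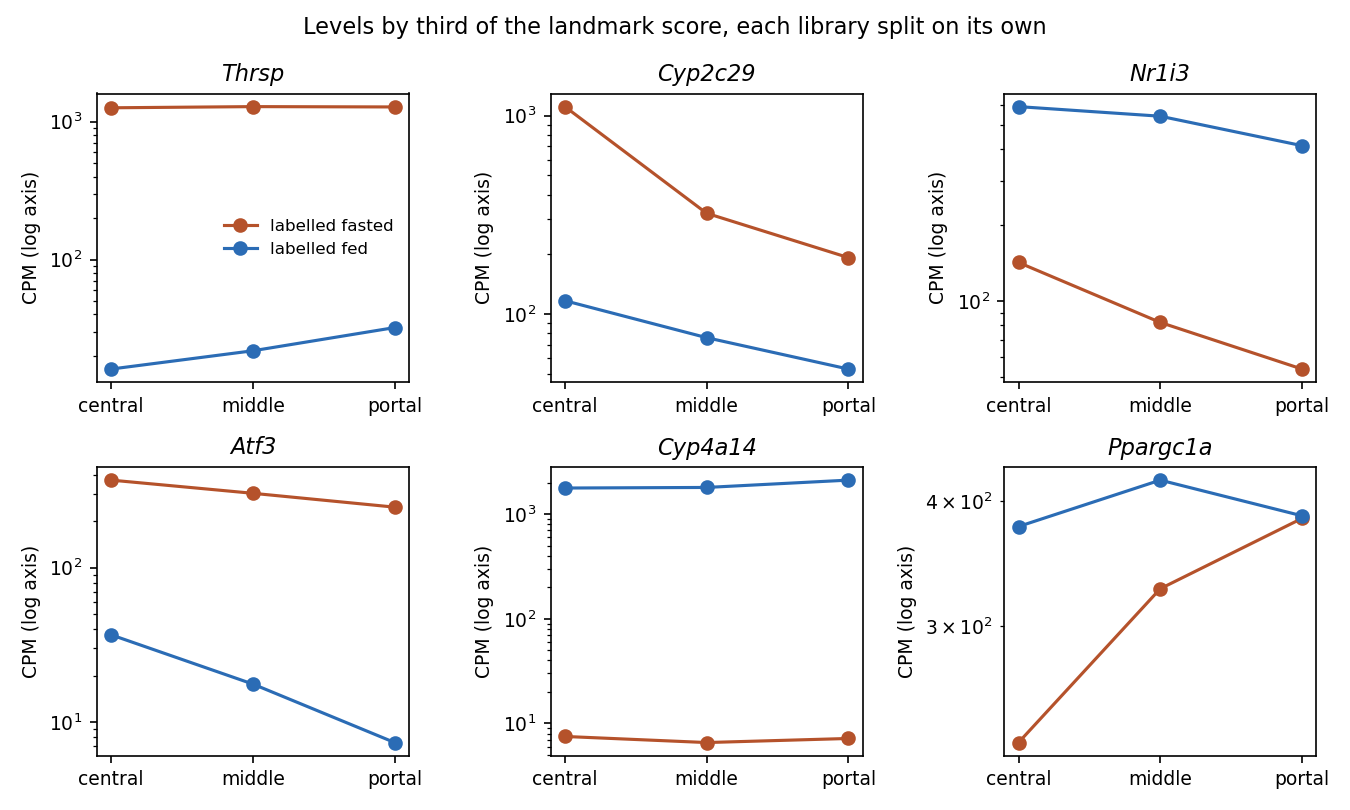
CPM in the central, middle and portal bins of hepatocyte-like nuclei for Thrsp, Cyp2c29, Nr1i3, Atf3, Cyp4a14 and Ppargc1a on log axes, with 1 line per library. Thrsp in the library labelled fed was at 16.0 CPM in the central and 32.1 CPM in the portal bin, and Atf3 in the same library at 36.7 and 7.37 CPM.

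Other cell classes were compared in endothelial-like and stellate-like nuclei. The genes with the largest ratios there included lipogenic and PPARA target genes of hepatocytes. In endothelial-like nuclei Thrsp (2614 and 11 UMIs) had a log2 ratio of 5.67 (4.83 to 6.68), and Cyp4a14 of -8.37 (-9.29 to -7.59). In stellate-like nuclei Cyp2c70 (368 and 1 UMIs) had a log2 ratio of 8.06 and Cyp4a14 -7.57. Hepatocyte RNA, measured from Alb, Apob, Mug1 and Cps1, stood in endothelial-like nuclei at 83.7% and 115% of its level in hepatocyte-like nuclei, and in stellate-like nuclei at 80.2% and 98.8%. Across genes, the log2 ratios correlated with those of hepatocyte-like nuclei (Pearson r 0.787 over 5569 genes and 0.739 over 4026 genes), although genes are not independent replicates.

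Genes at 5 times the level that hepatocyte RNA would bring, or more, numbered 175 and 509 where 1 library sufficed. They numbered 144 and 435 where both had to pass. Whether that RNA was free or came from doublets or misplaced nuclei was not told apart. In endothelial-like nuclei all 15 class markers measured were lower in the library labelled fasted, with a median of -1.16. The median over all 5569 genes there was 0.02, so the low ratios of single genes are not separate from a fall of the markers as a set. Deep barcodes weigh more in these sums: 310 nuclei of the library labelled fasted held 2096978 UMIs at a median of 2365. In the library labelled fed 111 nuclei held 457955 UMIs at a median of 1981. Whether a few deep barcodes or doublets lowered the markers was not tested. Of genes that passed in both libraries, Gas7 (1.98, on 55 and 3 UMIs) had the highest ratio and Adam23 (-2.35) the lowest. Dcn, a matrix proteoglycan of fibroblasts, was lower still (-2.75), but passed in the library labelled fed alone. Its 21.7 CPM in the library labelled fasted compare with 9.33 CPM expected from hepatocyte RNA. In stellate-like nuclei 6 of 14 class markers were lower in the library labelled fasted, and the highest genes that passed in both included Clstn2 (3.55, on 177 and 11 UMIs), Myh11 (3.27), a smooth muscle myosin, and Adamts9, a secreted protease (3.03). The lowest there were Tmem100 (-2.81) and Id3, a BMP target gene (-2.33). There were 310 and 111 endothelial-like and 168 and 124 stellate-like nuclei, so single genes rest on few counts.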

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

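The tests of exchanged labels and of 24 h fasting as labelled, and the shares of the set with Onecut1 over all 5105 nuclei, were chosen only after the result was seen; the other tests were set before.

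Dcn, which encodes decorin, had a log2 ratio of -2.75 in endothelial-like nuclei and 0.35 in hepatocyte-like nuclei, a difference of -3.10; it stood out because the directions were opposite in the 2 classes, and the difference was not tested. In stellate-like nuclei, of which it is a marker, it was also lower in the library labelled fasted (2439 against 4976 CPM), and RNA carried over from those nuclei was not ruled out.

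Genes of the fed state were high and PPARA targets low in the library labelled fasted. A 24 h fast as labelled would need PPARA targets above 0, and their median was -2.76 (-4.23 to -1.18). That median is part of the pattern itself, so it restates the pattern and is no separate test. Free cytoplasmic RNA as the whole cause would need the gap of 4.52 between the SREBP1 and ChREBP median and the PPARA median to shrink. In the nuclei with the least mitochondrial RNA it had to fall below 2.26, and it was 4.24 there. That result cannot exclude free RNA, because how much of it those nuclei still held was not measured. Hepatocyte genes also had the same directions in endothelial-like nuclei (Thrsp 5.67, Cyp4a14 -8.37), where free RNA may carry them. Exchanged library labels may account for the pattern: 3 of 5 textbook fasting lists lay opposite to the labels and 0 with them. These 3 were the SREBP1 and ChREBP, other PPARA target and fatty acid oxidation lists. They include the lists that define the pattern, so this count largely restates it and is no separate test either. With TMM scaling the hormone list, at 0.66 (0.26 to 1.33), lay with the labels, a reading adopted after that value was seen. TMM shifts every ratio by 1 constant, however. Before that shift the hormone list median of 0.23 lay at percentile 94.2 of matched random lists, within their range of -0.47 to 0.30. The hormone list therefore did not stand apart from matched genes. The question stays open because with 1 library per group an exchange cannot be told apart from any other difference between the pools.

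Oxidative phosphorylation genes were low in the library labelled fasted. If free cytoplasmic RNA, which the library labelled fed may carry more of, were the cause, the median of -1.08 should shrink past -0.54 in nuclei with at least 1000 genes and at most 1% mitochondrial counts. It was -0.46 there, which meets that bound, but its interval of -0.63 to -0.29 spans it, and the choice to read the interval was made after seeing it. Hepatocyte-like nuclei with at most 1% mitochondrial counts also differed in median depth, at 6938 and 14950 UMIs in the libraries labelled fasted and fed. Between 1 and 2% mitochondrial counts the median was -0.90, and between 4 and 5% it was -0.92. The library labelled fed had the higher mitochondrial share (2.56% against 1.68%). It also had more of the nuclear RNA Malat1 (34960 against 19400 CPM), which more cytoplasmic RNA would not by itself bring. Free RNA and a difference between the animals cannot be told apart here, and no biological explanation was tested.

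Clusters of hepatocyte-like nuclei of the library labelled fasted were grouped into 2 sets, 1 of clusters with Onecut1, a hepatocyte transcription factor, among their leading genes, with 1917 of 4586 nuclei (41.8%), after 519 of 5105 nuclei, 510 of them in a low-depth cluster, were left out. In that set Onecut1 was at 780 against 111 CPM and Cyp7b1 at 3397 against 670 CPM, in clusters drawn from these same counts. Position in the lobule would need shares over 50 points apart, and they differed by -11.5 points between the portal (34.5%) and central (46.0%) bins; depth per nucleus gave -7.30 points, and over all 5105 nuclei, the low-depth cluster included, these were -7.80 and 5.13 points, all within the 25 points set as the bound against them. Pooled animals in different states could produce such sets. A score compared, per nucleus, UMIs of the genes highest in the set with Onecut1 with UMIs of those highest in the other set. Of 478 endothelial-like and stellate-like nuclei of that library, 212 had at least 10 UMIs of these genes, and 62.7% of these 212 scored above 0. Among nuclei with that many UMIs, 99.6% did in the set with Onecut1 and 33.0% in the other set. A share between these values is no sign of 2 animals, because hepatocyte RNA found in those nuclei holds those genes too. Without a label of the animal per nucleus, pooled animals in different states cannot be told apart from other causes and remain a hypothesis.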

How the results depend on the processing

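The alternative without the 5% of nuclei with the highest doublet scores, and those that left out low-depth clusters, clusters with another class's marker among their leading genes, or nuclei outside matched depth and mitochondrial share, and the rule on free hepatocyte RNA in both libraries, were chosen after seeing the data. Of 25 list medians, 7 had an interval that excluded 0, and 6 of these kept their direction in all 15 alternatives. For the SREBP1 and ChREBP list the medians ranged from 1.75 to 2.20, for SREBP2 from 1.84 to 2.31, and for other PPARA targets from -3.00 to -2.31. Of 120 named genes, 111 kept their direction in every alternative. Of 375 alternative list medians, 356 stayed within the interval, 16 moved and 3 reversed. Of 1560 values of named genes, 1014, 533 and 13 did so. Reversed counts a change of direction only where the main interval excluded 0. Without that condition, 9 of 25 list medians and 9 of 120 named genes changed direction in at least 1 alternative. Of 320 zonal gene differences, 32 moved and 3 reversed. Of 48 class shares 16 moved, and of 42 shares with a UMI 35 moved, since less thinning leaves more UMIs per nucleus. With no replicate, depth limits only counting error; 1962 barcodes of the library labelled fed were over the mitochondrial limit.

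TMM and DESeq2 scaling shift every log2 ratio by 1 constant, and the following changes come from that construction. With TMM and DESeq2 scaling in turn, the medians were -0.76 and -0.76 for fatty acid oxidation, 0.32 and 0.33 for the urea cycle, 0.65 and 0.65 for periportal landmarks, 0.35 and 0.36 for the clock, 0.42 and 0.43 for autophagy, -0.65 and -0.64 for oxidative phosphorylation, and 0.77 and 0.78 for sex chromosome genes. The plasma protein list reversed to 0.12 and 0.13. Among named genes whose main interval excluded 0, those reversed were Pck1 (0.41 and 0.42), Ppargc1a (0.086 and 0.094), Cpt1a (0.057 and 0.064), Agpat2 (0.18 and 0.18) and Ebp (0.28 and 0.29). Eif2s3y and Kdm5d also turned under TMM scaling, as given above.

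With nuclei of at least 1000 genes and at most 1% mitochondrial counts, 636 and 195 hepatocyte-like nuclei were left, 89.8% and 99.5% of those kept. No cluster was named endothelial-like or stellate-like there, so these shares were 0% in both libraries, but 72 of 708 nuclei of the library labelled fasted (10.2%) and 1 of 196 of the library labelled fed lay in unnamed clusters, so how many cells of these classes remained is not known. The acute phase median moved to 0.57 and oxidative phosphorylation to -0.46, and the plasma protein list reversed to 0.23. Pck1 (0.23), Ebp (0.15) and Hspa8 (0.35) also reversed. With no filter the library labelled fed had 4.30% endothelial-like and 92.1% hepatocyte-like nuclei. At Leiden resolution 0.4 the library labelled fasted had 81.5% hepatocyte-like and 2.33% stellate-like nuclei, and at 2.0 it had 2.30% stellate-like. For each of these the cause was not tested. Without the clusters with Onecut1 or Rgs5 among their leading genes, genes that moved included Cyp2c70 (5.24), Pklr (2.98) and Lifr (1.62), which are also among the leading genes of the clusters with Onecut1.

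With a zonal score without genes of fasting lists, the portal minus central difference reversed for Igf1 (0.094) and Cyp7b1 (0.20) and moved for acute phase (-0.41), plasma proteins (-0.41), glycogen (0.24), oxidative phosphorylation (-0.36) and female-biased genes (-0.26); the cause was not tested. With 5 bins Acsl4 reversed to -0.052, SREBP2 moved to -1.13 and plasma proteins to -0.29; outer bins then lie farther apart, and the cause was not tested for Acsl4. In endothelial-like nuclei Rbms3 (1.45, 0.01 to 3.38, on 51 and 4 UMIs) reversed to -0.35 with doublets kept, which regrouped the nuclei (293 in place of 310 in the library labelled fasted). Leaving out genes that free hepatocyte RNA could carry moved the median of the 5 highest endothelial genes to 1.45, of the 5 lowest to -2.04, and of the 5 lowest stellate genes to -2.21; with the rule in both libraries these were 0.17, -1.93 and -2.17. This is by construction, since hepatocyte genes were removed.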

Other observations

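A planned test of the main pattern by thinning was dropped after the table of alternatives had been seen; there the thinned medians were 1.84 for the SREBP1 and ChREBP list and -2.68 for other PPARA targets.

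The set of hepatocyte-like nuclei with Onecut1 among its leading genes in the library labelled fasted also had more Zbtb7c, a transcription factor gene (293 against 41.2 CPM), Cyp2c68 (512 against 87.4 CPM), Cyp2c67 (476 against 96.8 CPM) and Hsd3b5 (162 against 51.4 CPM). The other set had more Etnppl, a phospholyase (535 against 195 CPM), Nrg4, a growth factor gene (315 against 104 CPM), Setdb2, a histone methyltransferase (281 against 85.5 CPM), Pgm3 (154 against 45.2 CPM), Slco1a4, an organic anion transporter (145 against 48.0 CPM), and Srd5a1, a steroid reductase (121 against 44.4 CPM). In list medians the sets differed most for 5 female-biased genes, by 0.95 (-0.87 to 1.72), an interval that spans 0. The differences were -0.28 (-0.47 to -0.04) for bile acid genes, -0.23 (-0.48 to -0.05) for xenobiotic genes and 0.23 (-0.16 to 1.32) for the growth hormone list. Since the sets were drawn from these same counts, the ratios have no error that covers that choice.

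Other lists differed along the lobule by less than the SREBP2 list. The portal minus central median was -0.24 (-0.36 to -0.10) for acute phase genes, -0.24 (-0.27 to -0.20) for plasma proteins, -0.21 (-0.51 to -0.09) for xenobiotic genes and -0.14 (-0.20 to -0.07) for oxidative phosphorylation, and -0.41 (-2.08 to -0.27) for 5 female-biased genes. Of 25 lists, 7 had an interval that excluded 0, as did 39 of 80 named genes. For genes these intervals cover counting error only, and the 5th and 95th percentiles over 9553 genes were -0.53 and 0.59. Nr4a1, which had 2.36 in the central bin and 3.69 in the portal bin, differed with Atf3 and Fos, and Pck1 hardly differed (-0.10, -0.15 to -0.05). In the library labelled fasted Nr4a1 also did not rise toward the portal bin (110.5 and 90.4 CPM).

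In stellate-like nuclei further genes stood above the level expected from hepatocyte RNA in both libraries. They included Pcdh18 (3.16, on 49 and 4 UMIs) on the high side and Mustn1 (-2.17) on the low side. In endothelial-like nuclei Plcb4 (-2.04) and Anapc15 (-1.93) were among the lowest such genes, where the class markers were low as well. Among further named genes of hepatocyte-like nuclei, Hyou1, an endoplasmic reticulum chaperone (1.63), and Uvrag, an autophagy regulator (1.03), were higher in the library labelled fasted, while Nqo1, a target of NRF2 (5 and 74 UMIs, -4.14), Sesn2, a stress sensor (-2.32), and Mt2, a metallothionein (-1.94), were lower.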
